A study of Mus musculus with 6 samples.

How the data were processed

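RNA from long-term hematopoietic stem cells (LT-HSCs) of WT mice and of Lxn-/- mice was measured on Affymetrix mouse Gene ST arrays, with 3 arrays per genotype. Per the series' design text, each array received RNA of a separate biological sample of about 100000 sorted cells pooled from 10 to 20 mice. The p-values of single genes therefore measure the spread between pools. Per the labels' protocols, total RNA was isolated on a spin column and 100 ng was turned into biotin-labelled cRNA. The values used here are log2 expression values that the authors normalized by robust multi-array average (RMA), per the design text and the submitters' processing notes, which name RMA and Partek 6.0. The scale was checked on the deposited values, which lay in the range of log2 RMA output and were neither centred per gene nor given as ratios. The background step, the summary level and the version of the probe set definitions are not given in the sources used here. The median of the log2 values was 7.90, 7.82 and 7.77 in WT replicates 1, 2 and 3 and 7.91, 7.86 and 7.86 in Lxn-/- replicates 1, 2 and 3. The number of arrays limits the precision.

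The deposited table held 35557 probe sets. GEO's platform annotation paired 21789 of them with 1 gene symbol and 1621 with several, and left 12147 unnamed here. Symbols were updated through Entrez identifiers for 23 probe sets, with a RefSeq gene table of assembly GRCm38.p6 that served only for names and for the order of genes along a chromosome. Coordinates are not given, because the files name no genome build. The 23410 probe sets with a symbol were tested, and no gene was named from a probe set with several symbols. For gene lists, each of the 19920 genes was represented by its probe set with the highest mean over all 6 arrays. Values identical to those of another probe set occurred in 390 of the named probe sets.

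Genotypes were compared with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with default settings on the log2 values of all 6 arrays without covariates, as a two-sided test with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. The design text also names limma as the submitters' method. Differences are Lxn-/- minus WT on the log2 scale. Errors are standard deviations over 3 arrays where SD is written and limma's moderated standard errors where SE is written. Single values were also compared by an exact two-sided permutation test, in which 3 arrays against 3 cannot give a p below 0.1.

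Gene lists were compared by camera in limma with a preset inter-gene correlation of 0.01. Camera sets the genes of a list against all other genes, and Benjamini-Hochberg adjustment ran over the 39 lists tested. With this preset correlation its p-values take little account of how far the genes of a list vary together between pools. The lists covered stem cell, progenitor, cell cycle, apoptosis, adhesion, metabolic, stress and signalling genes and the markers of other blood and stromal cells. A list of the 20 protein-coding genes on each side of Lxn was among them. A list for X inactivation and Y-linked genes was described without a test, because it had fewer than 5 measured members. Of the 1105 list genes, 997 were measured. The same lists were run with the correlation estimated per list, on ranks, and with fry, which asks whether the genes of a list move on balance one way and does not compare the list with other genes.

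Genes were named by a rule. It took Lxn, Thbs1 and any passing gene of the flanking list. In each direction it took 12 genes with exactly 1 symbol, no predicted or clone name and no overlap between the 3 values of each genotype, those with the largest differences if they passed and otherwise those of lowest unadjusted p. From each list it took up to 4 passing members, or up to 2 of lowest unadjusted p where none passed. Other genes are said to have been chosen after their values were seen. The groups, tests, gene lists, naming rule and other settings were fixed before the data were examined. A list of plasma cell markers and the settings that use it were added afterwards. Further families, relations and tests chosen after the data were seen are named with the other observations.

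The limma step was tested on simulated data with the spread of these arrays, in which 200 of 23410 probe sets were changed. It recovered 83.5% of those changed 1.5-fold, 98.5% of those changed 2-fold and 100% of those changed 4-fold, with 8, 10 and 10 false calls. The simulated noise was independent between genes and arrays, with limma's moderated variances, and 200 changed probe sets ease the adjusted threshold. These shares therefore do not show what would be found in the real pools if few genes changed or if genes vary together. In a simulated list comparison, a shift of 0.2 in the mitosis list gave a camera adjusted p of 3.18e-15, and 0 lists were called without a shift. The simulated genes varied independently of each other, so this 0 does not show how often camera calls lists when genes vary together. On the real values, other splits of the 6 arrays called 5 to 16 lists. The other settings were quantile normalization, a shift of each array to a common median, removal of dim probe sets, all probe sets, eBayes with trend and robust settings, array weights, the replicate number as a block, the mean of all probe sets of a gene, other thresholds, the other list tests and the omission of each array in turn. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.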

Results

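The data set compared LT-HSCs, the bone marrow cells that sustain blood formation over a lifetime, between WT mice and mice lacking latexin (Lxn), an inhibitor of metallocarboxypeptidases. The question named by the series is which genes are expressed differently in these cells after deletion of latexin. Cells were sorted from the marrow of female C57BL/6 mice aged 8 to 12 weeks as negative for lineage markers and CD34, positive for Sca1 and c-Kit, and negative for a marker that the labels call Flt2. Each genotype was represented by 3 pools, each measured on 1 array. Arrays of the same genotype were no more alike than arrays of different genotypes, with a mean correlation over probe sets of 0.995 within WT, 0.995 within Lxn-/- and 0.996 between genotypes. The first principal component held 38.8% of the variance, and its scores were -10.6, 2.63 and 23.3 in the WT pools and -12.6, 7.97 and -10.7 in the Lxn-/- pools.

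The signal of Lxn itself was lower in the Lxn-/- pools, with 8.74 ± 0.07 (SD, n = 3) against 9.21 ± 0.30 (SD, n = 3) in WT. The difference was -0.47 (SE 0.14, 95% confidence interval -0.79 to -0.15), or 1.39-fold. All 3 Lxn-/- values, 8.66, 8.78 and 8.78, lay below all 3 WT values, 8.99, 9.09 and 9.55. The exact permutation p was 0.1, the smallest that this design allows, and in limma the unadjusted p was 0.0101 and the adjusted p 0.993. Per the labels, exons 2 to 4 of the gene are deleted, and where the probes of this probe set lie is not given in the sources used here, so probes outside the deleted part check nothing. Without WT replicate 3 the difference was -0.30.

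No gene could be called different between the LT-HSCs of Lxn-/- and WT mice. No probe set passed an adjusted p of 0.05 in limma, where the lowest adjusted p was 0.993, and 0 passed at 0.1. At an unadjusted p under 0.05 there were 914 probe sets, 344 higher and 570 lower in Lxn-/-, where chance alone would give 1170. The 3 values of each genotype did not overlap for 2102 probe sets, or 8.98%, against 10% by chance. The median half-width of the 95% confidence interval was 0.194, and for 99.2% of the probe sets the interval lay within 1 log2 unit of 0 on either side. Every gene named here therefore had a difference that did not pass the test over all genes, and the values that follow describe these 6 pools. Thbs1, which encodes the matrix glycoprotein thrombospondin 1, had 11.11 ± 0.30 (SD, n = 3) in WT and 11.03 ± 0.67 (SD, n = 3) in Lxn-/-, a difference of -0.073 (SE 0.31), which ranged from -0.36 to 0.29 when single arrays were left out.

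Among genes with no overlap between genotypes, those of lowest unadjusted p and lower signal in Lxn-/- included several known from B cells and plasma cells. This grouping was made after the values were seen. Mzb1, an endoplasmic reticulum protein of antibody-producing cells, differed by -0.80 (SE 0.12) and Pou2af1, a B cell transcriptional coactivator, by -0.74 (SE 0.12). Sdc1, the plasma cell surface proteoglycan syndecan 1, differed by -0.48 (SE 0.08), the protein disulfide isomerase gene Txndc5 by -0.48 (SE 0.083) and Derl3, a factor of endoplasmic reticulum associated degradation, by -0.57 (SE 0.11). The widest gap was that of Lrmda, with 10.23 in WT, 8.76 in Lxn-/- and a difference of -1.47 (SE 0.27). The receptor gene Gpr55 differed by -0.58 (SE 0.091), Gpr155 by -0.60 (SE 0.10), the keratin gene Krt222 by -0.40 (SE 0.069), the sialyltransferase gene St6gal1 by -0.44 (SE 0.075), the nucleotidase gene Entpd4 by -0.45 (SE 0.083) and Ly6k by -0.36 (SE 0.068). Unadjusted p-values of these 12 genes in limma ran from 0.000162 to 0.000773.

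In the other direction, Bhlhe40, a transcriptional repressor induced by many stimuli, differed by 0.48 (SE 0.11). Map1lc3a, which encodes an autophagosome membrane protein, differed by 0.34 (SE 0.072), the zinc finger gene Zfp931 by 0.37 (SE 0.081) and the small nucleolar RNA Snord61 by 0.34 (SE 0.074). Differences were 0.31 (SE 0.076) for Angpt2, which encodes a ligand of the receptor Tek, and 0.41 (SE 0.089) for the metalloproteinase gene Mmp27. The remaining 6 were the pheromone receptor gene Vmn2r70 (0.66), Mir192 (0.61), the deubiquitinase gene Usp17la (0.44), Mir687 (0.43), Mirlet7f-1 (0.42) and the odorant receptor gene Olfr1076 (0.37). Of these 12 genes, 8 had means in both genotypes below 6.90, the 95th percentile of odorant and pheromone receptor probe sets in Lxn-/-, against 0 of the 12 lower ones.

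**Figure D1:**
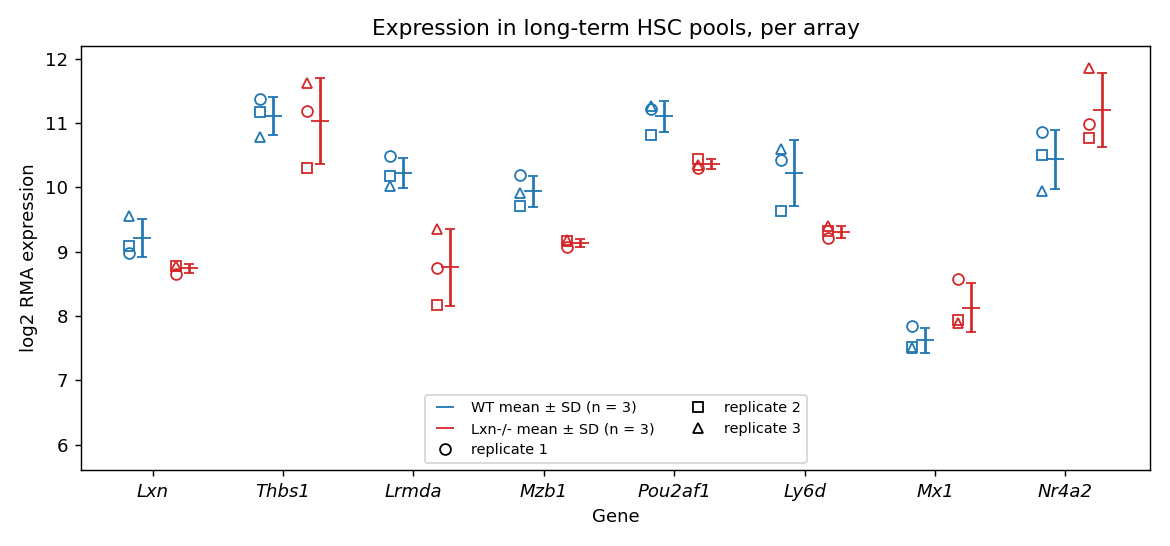
Log2 RMA expression (vertical axis) of 8 genes in each of the 6 arrays, with open symbols for single pools and bars for the mean ± SD of 3 WT (blue) and 3 Lxn-/- pools (red). The 3 Lxn values in Lxn-/- lie at 8.66, 8.78 and 8.78, below the WT values of 8.99, 9.09 and 9.55.

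As groups, immediate early genes were higher in Lxn-/- and the markers of B cells, the genes of mitosis and the markers of erythroid cells were lower. Camera called 10 of the 39 lists with its preset correlation and 8 on ranks, and 0 lists with an estimated correlation and 0 with fry, where 0 and 1 lists had an unadjusted p under 0.05. With an estimated correlation the lowest adjusted p over all lists was 0.609.

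Immediate early and dissociation stress genes, which cells induce within minutes of a stimulus, were higher in Lxn-/- for 24 of 27 members, with a median of 0.28 (camera adjusted p = 4.24e-12, adjusted p = 0.609 with an estimated correlation). The phosphatase gene Dusp2 differed by 0.38 (SE 0.10) and Ccn1, a matricellular protein gene, by 0.37 (SE 0.11). The value of the list against other genes was 0.32, and 0.16 without WT replicate 3. Quiescence regulators, which share Btg2, Egr1, Nr4a1 and Nr4a2 with that list, were higher for 12 of 18 members with a median of 0.081 (camera adjusted p = 0.00985, adjusted p = 0.609 with an estimated correlation). Cdkn1b, an inhibitor of cyclin-dependent kinases, differed by 0.24 (SE 0.09) and the nuclear receptor gene Nr4a2 by 0.77 (SE 0.31). This call was lost without WT replicate 3 (adjusted p = 0.0539) and without Lxn-/- replicate 3 (adjusted p = 0.120) in camera, where the list value of 0.16 became 0.094 and 0.11. It was also lost without dim probe sets, where the value was 0.15, and on ranks (adjusted p = 0.0504 and 0.0557).

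Targets of NF-kB, the inflammatory transcription factor, were higher for 18 of 23 members with a median of 0.09 (camera adjusted p = 0.000363, adjusted p = 0.609 with an estimated correlation). Nfkbiz, a nuclear cofactor of NF-kB, differed by 0.42 (SE 0.16) and the chemokine gene Cxcl10 by 0.22 (SE 0.10). Interferon response genes were higher for 27 of 33 members with a median of 0.083 (camera adjusted p = 0.000114, adjusted p = 0.609 with an estimated correlation). The antiviral genes Mx1 and Oas2 differed by 0.51 (SE 0.19) and 0.51 (SE 0.21). Without WT replicate 3 the NF-kB call was lost (camera adjusted p = 0.259) and its list value of 0.18 became 0.055, while array weights gave 0.11. Without Lxn-/- replicate 1 the interferon call was lost (camera adjusted p = 0.110) and its list value of 0.12 became 0.057.

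Genes of TGF-beta and BMP signalling were higher for 20 of 30 members with a median of 0.031 (camera adjusted p = 0.0325, adjusted p = 0.609 with an estimated correlation). Id1, a target of BMP signals, differed by 0.28 (SE 0.084) and Skil, a repressor of SMAD proteins, by 0.46 (SE 0.18). Genes of ribosomal proteins were higher for 25 of 33 members with a median of 0.053 (camera adjusted p = 0.00783, adjusted p = 0.609 with an estimated correlation), with 0.15 (SE 0.071) for Rps13 and 0.16 (SE 0.10) for Rps12. The ribosomal call was lost without WT replicate 3 or Lxn-/- replicate 2 (camera adjusted p = 0.113 and 0.103), with list values of 0.036 and 0.051 against 0.065. The TGF-beta call was lost without WT replicate 1 or Lxn-/- replicate 2 or 3 (camera adjusted p = 0.432, 0.103 and 0.133), with list values of 0.045, 0.057 and 0.061 against 0.070. It was also lost without dim probe sets, where the value rose to 0.078, with array weights, where it was 0.048, and on ranks (camera adjusted p = 0.0504, 0.191 and 0.0617).

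B cell markers were lower in Lxn-/- for 18 of 19 members, with a median of -0.23 (camera adjusted p = 5.99e-07, adjusted p = 0.609 with an estimated correlation). Adjusted over the list alone, 1 member passed in limma, Pou2af1, and Ighm, the constant region of the IgM heavy chain, differed by -0.38 (SE 0.11). Of the 39 lists, this was the only one with a member that passed when p-values were adjusted over the list alone. The list value against other genes was -0.26, and -0.15 with array weights. Erythroid markers were lower for all 16 members with a median of -0.29 (camera adjusted p = 0.000121, adjusted p = 0.651 with an estimated correlation). Alas2, the first enzyme of heme synthesis in red cells, differed by -0.27 (SE 0.12) and Trim10 by -0.24 (SE 0.11). That call was lost without WT replicate 3 (-0.12, camera adjusted p = 0.0896) and without Lxn-/- replicate 3 (-0.12, camera adjusted p = 0.226), against a list value of -0.30, and the value was -0.50 without Lxn-/- replicate 2.

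Genes of mitosis were lower for 32 of 34 members with a median of -0.15 (camera adjusted p = 7.18e-06, adjusted p = 0.766 with an estimated correlation). Ube2c, a ubiquitin-conjugating enzyme of mitotic exit, differed by -0.29 (SE 0.13) and the kinesin gene Kif20a by -0.27 (SE 0.14). The list value was -0.14, and -0.072 without WT replicate 3 (camera adjusted p = 0.0173), -0.23 without Lxn-/- replicate 2 and -0.042 without Lxn-/- replicate 3 (camera adjusted p = 0.521). Heat shock and unfolded protein response genes were lower for 17 of 25 members with a median of -0.06 (camera adjusted p = 0.012, adjusted p = 0.609 with an estimated correlation). The members of lowest p were Pdia4, a disulfide isomerase gene, at -0.33 (SE 0.073) and Xbp1, a transcription factor of secretory cells, at -0.39 (SE 0.10), beside a B cell marker median of -0.23. Plasma cell markers, a list added after the data were seen, had a median of -0.33 and share Dnajb9, Herpud1, Pdia4 and Xbp1 with this list, whose value of -0.059 was -0.03 without B cell and plasma cell genes (camera adjusted p = 0.174). That call was lost without WT replicate 1 or Lxn-/- replicate 2 or 3 (camera adjusted p = 0.434, 0.055 and 0.114), where the list value of -0.059 became -0.0057, -0.039 and -0.047. Without WT replicate 3 or Lxn-/- replicate 1 the value was larger in size, at -0.093 and -0.091 (camera adjusted p = 0.000728 and 0.00261). The call was also lost with quantile normalization, array weights and the mean of all probe sets (camera adjusted p = 0.0864, 0.176 and 0.0655), with values of -0.042, -0.027 and -0.046, and on ranks (camera adjusted p = 0.0985).

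**Figure D2:**
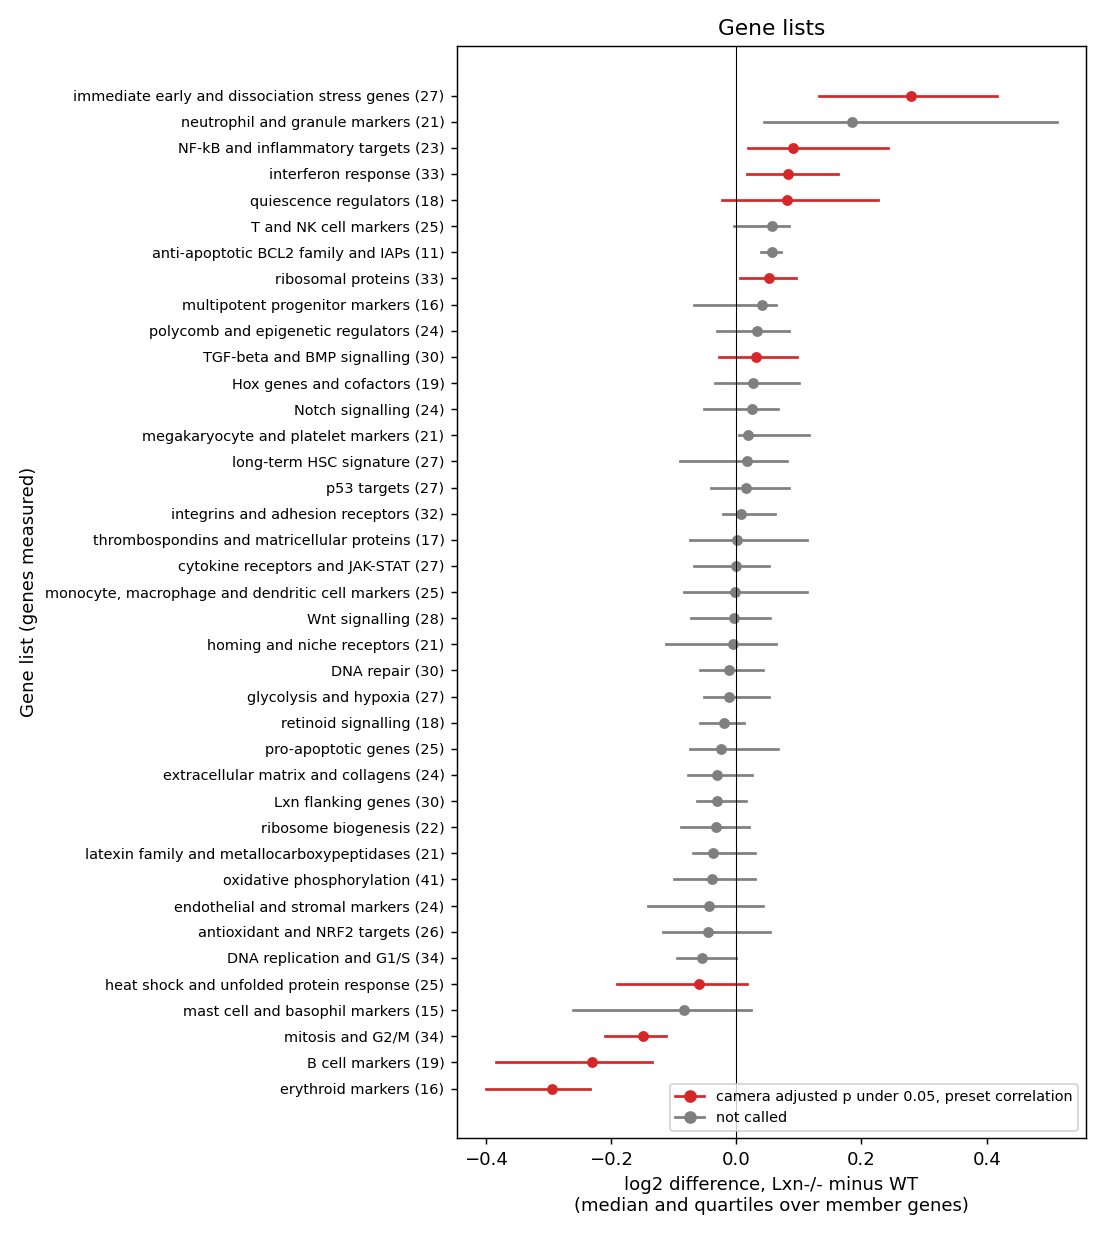
Median log2 difference, Lxn-/- minus WT (horizontal axis), for each of the 39 lists, with lines for the quartiles over member genes, the number of measured genes in brackets and red for the 10 lists that camera called with its preset correlation. Medians run from -0.29 for erythroid markers to 0.28 for immediate early genes, and 0 lists were called with an estimated correlation.

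The remaining 29 lists were not called, with camera adjusted p-values from 0.0551 to 0.998 and medians from -0.084 to 0.18. Genes of the long-term HSC signature had a median of 0.017 with 16 of 27 higher (camera adjusted p = 0.752), and Ndn and Ltb differed by -0.28 (SE 0.12) and -0.16 (SE 0.09). Multipotent progenitor markers had a median of 0.042 (camera adjusted p = 0.939), with -0.91 (SE 0.22) for Ly6d, a surface protein of lymphoid progenitors, and 0.12 (SE 0.089) for Cd48. Medians were 0.026 for Hox genes (adjusted p = 0.178), where Hoxa5 differed by 0.28 and Hoxa6 by 0.22, and 0.032 for polycomb and other epigenetic regulators (adjusted p = 0.083), where Dnmt3b differed by 0.18 and Tet2 by 0.19. DNA replication genes had a median of -0.054 (adjusted p = 0.233), and Tk1 and Rrm2, which supply nucleotides, differed by -0.21 and -0.25. That list was called lower without WT replicate 1 or Lxn-/- replicate 2 (camera adjusted p = 0.0102 and 0.00135).

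None of the lists of cell death and genome maintenance was called with all 6 arrays. Without WT replicate 1 the anti-apoptotic list was called higher (0.089 against 0.053, camera adjusted p = 0.026). Medians were 0.057 for anti-apoptotic genes (camera adjusted p = 0.135), -0.024 for pro-apoptotic genes (0.992), 0.015 for p53 targets (0.23) and -0.011 for DNA repair genes (0.998). At an unadjusted p under 0.05 in limma there were 4 of 27 p53 targets, 2 in each direction. Named members were Birc5 (-0.22) and Mcl1 (0.12), Tradd (-0.18) and Fas (0.20), Plk3 (0.52) and Trp53inp1 (-0.19), and Lig4 (-0.29) and Ercc1 (-0.11).

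Genes of adhesion and the niche were likewise not called. Thrombospondins and other matricellular genes had a median of 0.0012 (camera adjusted p = 0.441), with 0.37 for Ccn1 and -0.15 for Ccn3. The median was 0.008 for integrins and adhesion receptors (adjusted p = 0.263), where Itga9 differed by 0.19 and Cdh2 by -0.34, and -0.0048 for homing and niche receptors (adjusted p = 0.992), where Casr differed by -0.23 and Ackr3 by -0.19. Matrix and collagen genes had a median of -0.03 (adjusted p = 0.765), with 0.13 for Lama5 and -0.12 for Fbln2. Metallocarboxypeptidases of several kinds and relatives of latexin had a median of -0.037 (adjusted p = 0.74), with -0.17 for Cpxm2 and -0.18 for Cpz. The 30 measured genes flanking Lxn had a median of -0.031 (adjusted p = 0.992), with 0.60 for Tiparp and -0.16 for Otol1.

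Among metabolic and signalling lists, medians were -0.039 for oxidative phosphorylation (camera adjusted p = 0.394), -0.032 for ribosome biogenesis (0.625), -0.012 for glycolysis and hypoxia (0.765) and -0.045 for antioxidant genes (0.682). Their named members were Ndufs1 (-0.12) and Atp5g1 (-0.18), Rrp9 (-0.16) and Gar1 (-0.11), Egln3 (0.19) and Hk2 (0.26), and Gstp1 (-0.23) and Mt2 (-0.52). Oxidative phosphorylation genes were called lower without Lxn-/- replicate 2 (-0.068 against -0.025, camera adjusted p = 0.00543). Medians were -0.004 for Wnt signalling (adjusted p = 0.765), 0.025 for Notch signalling (0.48), -6.7e-05 for cytokine receptors (0.718) and -0.02 for retinoid signalling (0.74). The corresponding members were Lef1 (-0.33) and Fzd4 (0.14), Heyl (-0.20) and Jag2 (0.33), Socs3 (0.40) and Csf3r (0.18), and Aldh1a7 (-0.37) and Cyp26a1 (-0.19).

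Markers of other cells that a gate could hold were mostly not called. Neutrophil and granule markers had a median of 0.18 with 16 of 21 higher (camera adjusted p = 0.0551, adjusted p = 0.909 with an estimated correlation), and S100a8, an abundant neutrophil protein gene, differed by 0.75 (SE 0.76) and Csf3r by 0.18 (SE 0.13). The neutrophil list was called higher with quantile normalization (camera adjusted p = 0.00593), with a common median (0.000369), on ranks (0.0169) and without WT replicate 1 (0.000192), WT replicate 2 (0.0012) or Lxn-/- replicate 2 (0.000885), and called lower without WT replicate 3 (-0.20 against 0.29, camera adjusted p = 0.0173). The median was -0.0016 for monocyte, macrophage and dendritic cell markers (adjusted p = 0.765), although Cd74, the invariant chain of MHC class II, differed by -0.41 (SE 0.10) and the protease gene Ctss by -0.49 (SE 0.12). Medians were 0.057 for T and NK cell markers (adjusted p = 0.276), -0.084 for mast cell and basophil markers (0.438), 0.018 for megakaryocyte and platelet markers (0.0747) and -0.044 for endothelial and stromal markers (0.765). Megakaryocyte markers were called higher with quantile normalization (camera adjusted p = 0.0328) and with a common median (0.0408). T and NK cell markers were called higher without Lxn-/- replicate 3 (0.21, camera adjusted p = 0.000807) and lower without Lxn-/- replicate 2 (-0.13, camera adjusted p = 0.00125). Their named members were Klrb1c (0.31) and Klrk1 (0.37), Cma1 (-0.25) and Tpsab1 (0.21), Rap1b (0.18) and Cd9 (0.12), and Alpl (-0.34) and Nes (-0.16). Of the sex-linked genes, which were not tested as a list, Xist differed by 0.15 (SE 0.13) and Eif2s3y by 0.12 (SE 0.086) at 3.62 in WT. When single arrays were left out, Klrb1c ranged from -0.018 to 0.52 and Klrk1 from -0.0014 to 0.67. S100a8 then ranged from -0.14 to 1.40 and Xist from -0.0050 to 0.28.

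The spread between pools of one genotype was wide for several of these groups. The mean of the neutrophil markers relative to WT had an SD of 0.878 over the WT pools and 0.702 over the Lxn-/- pools, around a difference of 0.28 (exact permutation p = 0.6). For immediate early genes the difference of 0.31 had an exact permutation p of 0.2, for B cell markers that of -0.27 a p of 0.2, for mitosis that of -0.15 a p of 0.4, and for erythroid markers that of -0.31 a p of 0.4, all by exact permutation. Pool averages of the neutrophil markers, in relations chosen after the values were seen, ran with those of the immediate early genes (Pearson's r 0.853, Spearman's rho 0.886, exact permutation p = 0.0236 and 0.0333) and against those of the mitosis genes (r -0.912, rho -0.943, exact permutation p = 0.00972 and 0.0167) and the erythroid markers (r -0.944, rho -0.943, exact permutation p = 0.00556 and 0.0167). None of these 3 relations passed when adjusted over all 741 pairs of lists, with adjusted p = 0.246, 0.18 and 0.18 for r by exact permutation. With genotype means removed, r was 0.958, -0.950 and -0.982. Median, mean and camera direction differed in sign for 8 lists, none of them called, which were the cytokine receptor, long-term HSC signature, glycolysis, Wnt, monocyte, multipotent progenitor, flanking and DNA repair lists.

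**Figure D3:**
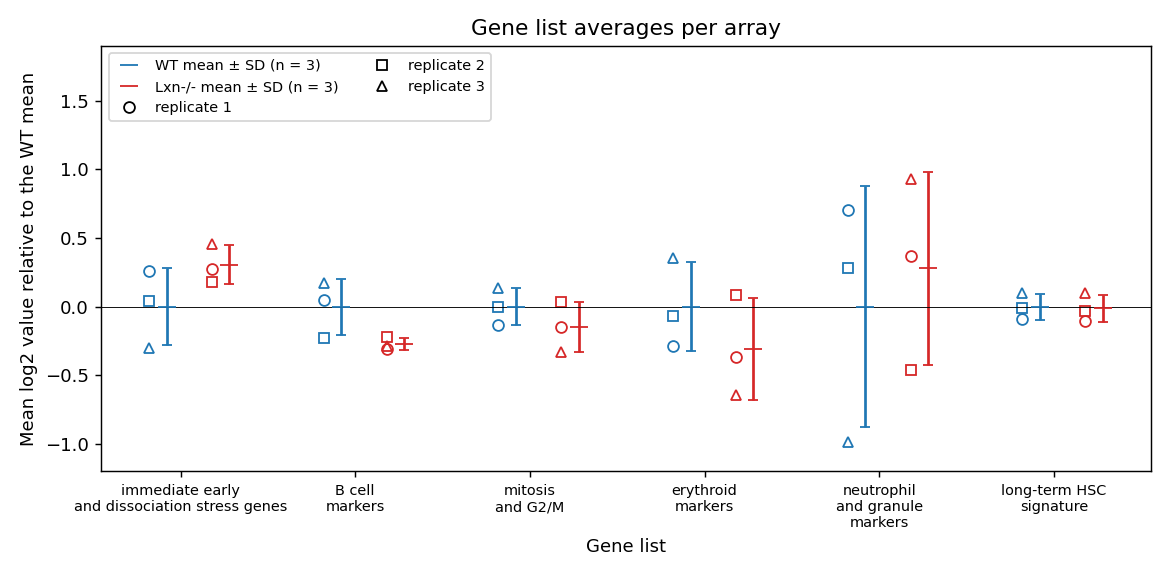
Mean log2 value of 6 lists in each array relative to the WT mean (vertical axis), with open symbols for pools and bars for the mean ± SD of 3 WT (blue) and 3 Lxn-/- pools (red). Neutrophil markers spread most, with an SD of 0.878 in WT and 0.702 in Lxn-/-, and each list shown has values that overlap between genotypes.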

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

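The comparison with B cell and plasma cell genes removed, and the use of the plasma cell marker mean as a covariate, were chosen after the data were seen. Under each planned normalization, filter, variance model and array omission, and with that covariate, limma called 0 genes at an adjusted p under 0.05, and 0 at 0.1 or with 1.5-fold added, beside 914 at an unadjusted p under 0.05. The plasma cell marker mean did not overlap between genotypes, so as a covariate it takes up much of the genotype difference. The 0 calls with it are therefore no check of the result. With an unadjusted p under 0.05 and at least 1.5-fold there were 36 probe sets, 4 higher and 32 lower. The lists called numbered 10, 7 to 12 without single arrays, 12 with either normalization, 8 without dim probe sets, with array weights, on ranks or without B cell and plasma cell genes, 9 with the mean of all probe sets, 0 with an estimated correlation and 0 with fry. The cause of these changes was not tested. None of the 10 called lists turned direction in any setting run. With the replicate number as a block, 0 genes and 10 lists were called and the adjusted p of Lxn was 0.911. Deviations from the genotype means correlated by 0.37, -0.072 and -0.08 between arrays with the same number. By these deviations 2 of the 6 arrays correlated best with their own number, and the numbers were not taken as pairs. On the values themselves, WT and Lxn-/- replicate 1 shared the same highest correlation (0.9973), and so did WT and Lxn-/- replicate 2 (0.9967). A batch shared by arrays of the same number therefore stays open. The calls gained with quantile normalization were neutrophil, megakaryocyte and polycomb genes (adjusted p = 0.00593, 0.0328 and 0.0134), and those with a common median neutrophil and megakaryocyte genes (adjusted p = 0.000369 and 0.0408). Further calls gained without single arrays were anti-apoptotic genes without WT replicate 1 (adjusted p = 0.026), DNA replication genes without WT replicate 1 or Lxn-/- replicate 2 (0.0102 and 0.00135), endothelial genes without WT replicate 2 (0.0436) and megakaryocyte genes without WT replicate 3 or Lxn-/- replicate 1 (0.00639 and 0.0106). T and NK cell markers gained a call without WT replicate 3 or Lxn-/- replicate 1 or 3 (0.0463, 0.0232 and 0.000807), Hox and oxidative phosphorylation genes without Lxn-/- replicate 2 (0.00709 and 0.00543) and monocyte genes without Lxn-/- replicate 3 (0.000709). Heat shock genes lost their call without B cell and plasma cell genes (adjusted p = 0.174), where -0.059 became -0.03. Signal over background limits dim probe sets, such as 8 of the 12 named genes that were higher.

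The direction of the list test turned in 30 of 467 list comparisons under other settings and in 35 of 234 without single arrays. The sign of the difference turned in 0 of 781 and 6 of 612 gene comparisons. Removal of dim probe sets, the test of all probe sets, the trend and robust settings and the block leave a gene's difference as it is. Under these settings no sign could turn, so much of the 781 is no check of stability. Camera weighs moderated t-values and not the mean log2 difference printed here, and fry and ranks give another value. This mean was therefore given for 22 of the 30 and changed sign in 5 of these 22, and in 16 of the 35. Under other settings 0 of the 30 passed, and without single arrays 2 of the 35 did, neutrophil markers without WT replicate 3 (adjusted p = 0.0173) and T and NK cell markers without Lxn-/- replicate 2 (adjusted p = 0.00125). The values that follow are mean log2 differences of a list against other genes, and the cause was not tested. With quantile normalization they were 0.0025 for ribosome biogenesis and 0.017 for homing receptors. With a common median, which cannot move this mean, they were -0.047 for endothelial, -0.00044 for pro-apoptotic, 0.0044 for homing and -0.0048 for DNA repair genes. Without dim probe sets they were -0.014 for the HSC signature, 0.0084 for glycolysis, -0.028 for monocyte, 0.057 for matrix, -0.054 for progenitor, 0.022 for homing and -0.016 for DNA repair genes. Array weights gave -0.017 for the HSC signature, 0.11 for endothelial, -0.017 for glycolysis, 0.032 for matrix, -0.068 for progenitor and 0.018 for homing genes. The block, which left the mean as it was, gave 0.016 for the flanking genes, and the mean of all probe sets gave 0.0028 for pro-apoptotic genes. Rank shares gave 0.0052 for homing and -0.010 for flanking genes. Fry, with the plain list mean, gave 0.0052 for glycolysis, -0.0082 for Wnt, -0.0059 for monocyte, -0.056 for progenitor, 0.0038 for flanking and -0.017 for DNA repair genes. Without B cell and plasma cell genes, DNA repair gave -0.0057.

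Without single arrays, Thbs1 ranged from -0.36 to 0.29, S100a8 from -0.14 to 1.40, Xist from -0.0050 to 0.28, Klrb1c from -0.018 to 0.52 and Klrk1 from -0.0014 to 0.67, while Lxn ranged from -0.58 to -0.30. Values of lists whose test turned, which need not cross 0, ranged from -0.052 to 0.044 for the HSC signature, -0.016 to 0.049 for glycolysis, 0.011 to 0.024 for flanking, -0.039 to 0.037 for DNA repair, -0.078 to -0.0021 for retinoid, -0.071 to 0.14 for monocyte and -0.021 to 0.015 for pro-apoptotic genes. They ranged from -0.20 to 0.66 for neutrophil, -0.092 to 0.025 for DNA replication, -0.18 to 0.10 for endothelial, -0.030 to 0.024 for matrix, -0.076 to -0.0085 for progenitor and -0.020 to 0.047 for homing genes. The last were -0.13 to 0.21 for T and NK cell, -0.068 to 0.018 for oxidative phosphorylation, -0.17 to 0.033 for mast cell, -0.050 to 0.016 for ribosome biogenesis and -0.099 to -0.013 for antioxidant genes.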

Other observations

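The plasma cell list, the choice of Cd34, Flt3 and Mpo, the immunoglobulin, microRNA, small nucleolar RNA and globin families, the relations between list averages, and the tests of exchanged labels, of array background for Lxn and of other splits for genes were chosen after the data were seen.

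Small nucleolar RNAs, which guide chemical modification of ribosomal RNA, were higher in Lxn-/- for 57 of 58 probe sets, with a median of 0.21 and of 0.18 and 0.16 under the other normalizations. Their mean relative to WT was 0.178, 0.0447 and -0.223 in the WT pools and 0.180, 0.267 and 0.254 in the Lxn-/- pools (exact permutation p = 0.1, the smallest possible). The genotypes overlapped under both other normalizations (exact permutation p = 0.2), and the difference of 0.23 was 0.12 without WT replicate 3. The globin genes were lower for 7 of 8 probe sets with a median of -0.35, and their genotypes overlapped (exact permutation p = 0.2). The median of 340 microRNA probe sets was 0.027 and turned to -0.0075 and -0.018 under the other normalizations.

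Across all 6 pools, the average of the neutrophil markers ran against that of the erythroid markers, with Pearson's r -0.944 (exact permutation p = 0.00556, adjusted 0.18) and Spearman's rho -0.943 (exact permutation p = 0.0167, adjusted 0.242). Neutrophil markers also ran against mitosis genes, with r -0.912 (exact permutation p = 0.00972, adjusted 0.18) and rho -0.943 (exact permutation p = 0.0167, adjusted 0.242), and with immediate early genes, with r 0.853 (exact permutation p = 0.0236, adjusted 0.246) and rho 0.886 (exact permutation p = 0.0333, adjusted 0.313). These 3 relations were picked from 741 pairs of lists, over which the p-values are adjusted, and none passed. Without the 2 pools farthest from the median, r was -0.818, -0.862 and 0.854. With the genotype means removed, r was -0.982, -0.950 and 0.958. Cd34, whose protein the gate excluded, and Flt3, which the labels do not name and which was chosen here, had signals of 13.1 ± 0.04 and 11.9 ± 0.14 (SD, n = 3) in WT and 13.2 ± 0.15 and 12.0 ± 0.35 (SD, n = 3) in Lxn-/-, at percentiles 98.7 and 95.1 in WT, and Mpo, a neutrophil granule enzyme gene, stood at percentile 99.2. Signal ranks depend on probe affinity and are not abundances.

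Immunoglobulin probe sets were lower in Lxn-/- for 28 of 32, with a median of -0.39 (-0.39 and -0.43 under the other normalizations). Their mean relative to WT was 0.0668, -0.159 and 0.0923 in the WT pools and -0.368, -0.193 and -0.453 in the Lxn-/- pools (exact permutation p = 0.1, the smallest possible). WT replicate 2 thus lay close to Lxn-/- replicate 2. A candidate explanation is that plasma cells were carried into the WT pools, or fewer into the Lxn-/- pools. Of 33 measured plasma cell markers, 30 were lower with a median of -0.33. Of them, 19 passed in limma adjusted over the list alone, though the list was partly chosen on these values. The 23 whose values had not been seen gave a median of -0.22 with 20 lower and 4 passing alone (camera p = 8.72e-12, p = 0.0331 with an estimated correlation, fry p = 0.0259). No other split gave these 23 a median beyond 0.151 in size. They were measured in the same pools as the genes that prompted the list, so they are not independent evidence. Pool averages of all 33 and of the 23 each had an exact permutation p of 0.1, the smallest possible. Of the antibody genes that plasma cells express strongly, Jchain differed by -0.30 and Igha, with a signal of 13.4, by -0.04 (SE 0.23), and 7 of the 41 genes of the list are members of other lists. Of the 36 probe sets with an unadjusted p under 0.05 in limma and at least 1.5-fold, 5 were immunoglobulin and 6 other plasma cell markers. While 4 were higher, the 32 lower ones also held Prg2 (-1.09), Alox15 (-0.95) and Il5ra (-0.78), chosen after their values were seen. Leaving out single WT pools kept at least 84.7% of the median of all 33 markers and 76.6% of that of the 23 unseen ones, which argues against 1 WT pool as the only source. Of 6 other blood cell lists, 3 had a median of 0 or above, the bound set beforehand against a lower share of stem cells in the WT pools. However, 0 of them were clear of their spread. The 6 lists also leave out the B cell markers, which were lower for 18 of 19 members with a median of -0.23. A lower share of stem cells in the WT pools therefore stays open. The lineage, Sca1 and c-Kit gates are meant to remove such cells, and a genotype difference in plasma cell number or in these transcripts per cell cannot be told apart from carry-over with these pools and was not tested.

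The Lxn difference of -0.47 was small for a deleted gene. With 0 of 3 Lxn-/- pools at or above the lowest WT value, an exchange of labels finds no misplaced pool, but the gap of 0.20 was smaller than the WT SD of 0.30, so such an exchange stays open. Array background alone is argued against as the source of the remaining signal, since the Lxn-/- mean of 8.74 lay above 6.90, the 95th percentile of odorant and pheromone receptor probe sets. Probes in the exons that remain may account for it, which could not be tested without probe positions. Gfm1, within whose span Lxn lies and which was chosen after its values were seen, differed by -0.06 (SE 0.10).

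The 6 pools allow 10 splits into 3 against 3, too few for a share under 0.05. The real split gave 0 genes by limma (914 at an unadjusted p under 0.05) and the highest other split gave 2. With a real count of 0, all 10 splits give as many whatever the data, so this count says nothing about chance. For lists the real split gave 10 and the highest other 16, and 6 of the 10 splits, the real one included, gave at least 10. The split of WT replicate 1 with Lxn-/- replicates 1 and 3 against the rest gave 2553 probe sets at an unadjusted p under 0.05, and that of WT replicate 1 with Lxn-/- replicates 1 and 2 gave 2377. These were the highest counts of the 9 other splits, which ran from 486 to 2553, and were picked after they were seen. The first of these splits parted the pools by the sign of the first principal component, with 38.8% of the variance. The other parted them by the sign of the second component, with 24.0%. Scores on the second were 3.15, -3.22 and -5.45 in the WT pools and 9.63, 13.2 and -17.3 in the Lxn-/- pools. The main structure among the pools therefore did not follow genotype. Its source was not tested. The counts do not single out 1 grouping.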
